A study of Mus musculus with 9 samples.

How the data were processed

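RNA-seq was measured in 9 libraries of intestinal cells from C57BL/6 mice at postnatal day 6. Per the labels, freshly isolated cells were dissociated, filtered and sorted on EphB2 with an APC-coupled antibody, and poly(A) RNA was turned into cDNA that was amplified by long-distance PCR, sheared and sequenced on an Illumina HiSeq. Per the labels, the authors made the counts per gene with HTSeq from reads aligned to mm10, and list CASAVA 1.4, FastQC, Bowtie2 and DESeq2 among their tools. The annotation, the strand setting, read filters and most tool versions are not given in the sources used here. Each deposited table holds whole-number counts for 24421 gene symbols and 5 summary lines, which stayed out of sums and tests. The counts were used as deposited, so reads shared by near-identical gene copies carry whatever rule the counting used.

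The 9 libraries had 1503972 to 2074076 reads in genes. At that depth 3 reads correspond to 1.37 to 2.002 CPM in a single library, and a fold against a group with 0 reads is given as a lower bound against a floor of 3 reads over that group. Ratios for groups with 1 to 3 reads carry a 95% interval of a ratio of counts. Groups follow the titles (genotype and sort), and no library was left out of the fit. Positions are those of GENCODE for GRCm38.

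All libraries were fitted together with edgeR 4.0.16 in R 4.3.3: filterByExpr by group kept 11577 genes, libraries were scaled by TMM, and the quasi-likelihood F test (two-sided, robust) used 4 group means with 5 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are called. SE is the log2 fold change over the square root of F. The comparisons were KO against WT in each sort, EphB2-positive against EphB2-negative cells in each genotype, and the difference of the genotype effect between the sorts. Gene lists were tested with limma's camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison, for lists with at least 3 tested members. The tests, the alternatives, 38 gene lists and the rule for named genes were chosen before the data were examined. These lists cover cell types, pathways and cells that the sort could carry along, and 33 had enough tested members.

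Named genes are Nfkbia and Ephb2, a fixed set of marker genes, the first 4 members by p-value of each list described, and for each comparison of 2 groups the 8 called genes with the highest and the 8 with the lowest log2 fold change. The last had to reach a mean of 10 CPM in the higher group with no overlap between libraries. For the difference of the genotype effect, 5 genes in each direction were taken by p-value. The rule allows genes to be left out where a paragraph would only list statistics. Some genes that the rule takes, a marker fixed by name among them, are not reported here; the other fixed markers are all printed. Which other list members to leave out was decided after their values were seen, and those printed are richer in genes that passed: for KO against WT, 58 of 84 printed against 82 of all 167 in EphB2-positive cells, and 69 of 85 against 105 of 168 in EphB2-negative cells.

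Alternatives were DESeq2's size factors in the same fit, no filter on low counts, a stricter filter of 5 CPM in 2 libraries, DESeq2 1.42.0, voom with quality weights, the libraries of the compared groups alone, the pan-leukocyte score (mean log2 CPM of the pan-leukocyte list) as a covariate, blocks on the replicate number and on a code in the names of the files, and leaving out each library in turn. Lists were also tested with an estimated correlation and with limma's fry. A crypt score (mean log2 CPM of the stem cell list minus that of the absorptive enterocyte list) as a covariate, and leaving WT EphB2-negative replicate 1 out of comparisons it is not part of, were chosen after seeing the data. The workflow was tested on simulated data with 2-fold and 4-fold changes at the depth of these libraries. Each gene had 1 baseline mean and 1 spread in all groups. So neither the sort effect nor the wider spread of the WT EphB2-negative pair was simulated. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.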

Results

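RNA was sequenced from freshly isolated intestinal cells of C57BL/6 mice at postnatal day 6, sorted by their surface level of EphB2. EphB2 is a receptor tyrosine kinase that is high on cells of the lower crypt and lost as cells move up the villus. The mice were wild type (WT) or lacked IκBα (KO), the product of Nfkbia, which binds NF-κB dimers and holds them in the cytoplasm. There were 9 libraries in 4 groups: WT EphB2-positive (n = 2), WT EphB2-negative (n = 2), KO EphB2-positive (n = 3) and KO EphB2-negative (n = 2). The libraries held 1503972 to 2074076 reads in genes, and 13120 to 15131 genes had at least 1 read. The series title asks whether loss of IκBα gives stem cells of the intestine features of the fetal gut. Values below are read counts scaled to a common library size and composition (CPM), as mean ± SD over the libraries of a group, and log2 fold changes are given ± SE. Intervals and floors cover counting error only, since the reads came from PCR-amplified cDNA without molecular identifiers. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples.

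Principal component 1 of log2 CPM held 62.7% of the variance and separated the sorts, and component 2, with 21.8%, separated the genotypes. WT EphB2-negative replicate 1 lay between the sorts on component 1, at -12.4 against 66.7 for replicate 2 of its group. Across genes, its log2 CPM had r = 0.941 with WT EphB2-positive replicate 1 and r = 0.863 with WT EphB2-negative replicate 2. The chi-square per degree of freedom between those WT EphB2-negative replicates was 24.2, against 1.93 to 4.32 for the other 5 replicate pairs.

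**Figure D1:**
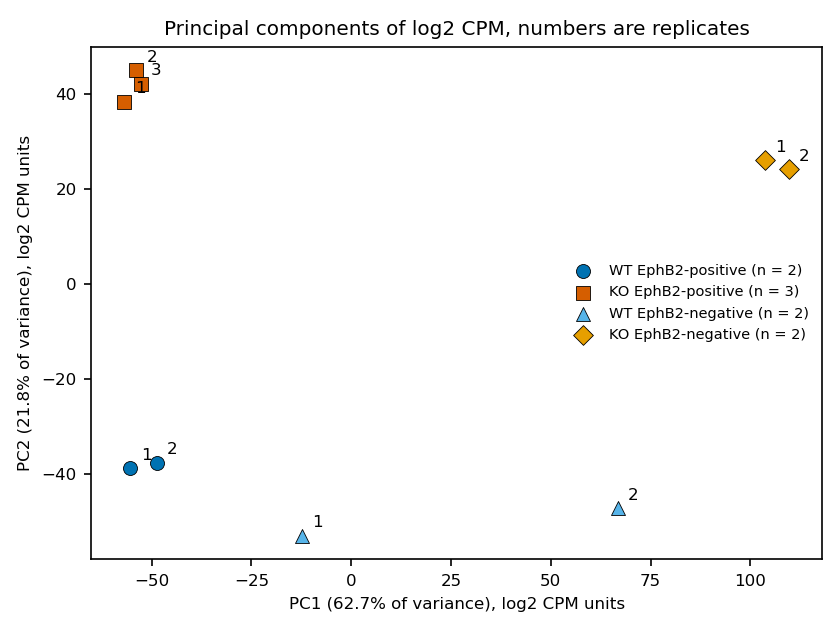
Principal components 1 and 2 of log2 CPM for the 9 libraries, each point a library, with axes in log2 CPM units and the share of variance in percent. WT EphB2-negative replicate 1 sits at -12.4 on component 1, between the EphB2-positive libraries, which lie at or below -48.7, and WT EphB2-negative replicate 2 at 66.7.

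Nfkbia (chromosome 12, 55489410 to 55492647 on GRCm38, minus strand) had 58 and 163 reads in the WT EphB2-positive libraries, 47 and 114 reads in the WT EphB2-negative libraries and 0 reads in each of the 5 KO libraries. Against the floor of 3 reads over a group, its level in KO was at least 101-fold lower in EphB2-positive cells (adjusted p = 0.015) and at least 40.02-fold lower in EphB2-negative cells (adjusted p = 0.022). Ephb2 (chromosome 4, 136647539 to 136835988, minus strand) stood at 151 ± 12.99 CPM in WT EphB2-positive and 95.7 ± 40.9 CPM in WT EphB2-negative cells, a difference that did not pass the test (log2 fold change 0.66 ± 0.24, adjusted p = 0.12). In KO it was higher in EphB2-positive cells, at 179 ± 6.83 against 32.5 ± 2.598 CPM (log2 fold change 2.45 ± 0.26, adjusted p = 9.2e-05). The WT EphB2-negative replicate 1 library held 124.6 CPM of Ephb2 and replicate 2 held 66.8 CPM.

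The first comparison asked what the sort separated in WT. The medians of the stem cell and cell cycle lists lay above 0, and that of the absorptive enterocyte list below 0, in EphB2-positive against EphB2-negative cells (n = 2 and 2). Most members of each did not pass over all genes, and the calls by camera were lost with an estimated correlation (adjusted p = 0.27, 0.37 and 0.27). Of single genes, Smo, the signal transducer of Hedgehog, rose to 54.4 ± 17.9 against 13.4 ± 1.55 CPM. Ptk7, a Wnt co-receptor, rose to 20.9 ± 3.77 against 5.12 ± 2.45 CPM, and Neurog3, the transcription factor that starts enteroendocrine fate, to 19.4 ± 5.16 against 4.45 ± 0.813 CPM. Gcg, which encodes proglucagon, also rose (log2 fold change 1.80 ± 0.27, adjusted p = 0.017). The mast cell proteases Mcpt1 and Mcpt2, close copies between which reads could be split, had 0 reads in EphB2-positive cells and were at least 591-fold and 365-fold lower there, and Cpa3 was at least 46.2-fold lower. Afp, the fetal serum protein alpha-fetoprotein, fell by 6.34 on the log2 scale (adjusted p = 0.0019). Among further genes taken by the rule, Serpina10, Tmem132a and Sorcs2 rose with log2 fold changes of 2.40 ± 0.51, 2.00 ± 0.41 and 1.83 ± 0.23. AI118078 rose with a ratio of 42.96 (counting interval 7.29 to 1738). Syn2 fell with a ratio of 0.0138 (counting interval 3.45e-04 to 0.0792), and Mcpt4 and Cx3cr1, with 0 reads in EphB2-positive cells, were at least 16.7-fold and 16.1-fold lower.

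By list, 3 of 24 tested intestinal stem cell genes rose, 0 fell and 21 did not pass, or 14 up and 0 down adjusted over the list alone. Their median log2 fold change was 1.24, camera gave adjusted p = 1.9e-10, with adjusted p = 0.27 for an estimated correlation. Of the absorptive enterocyte list, 0 of 25 tested rose, 11 fell and 14 did not pass, or 2 up and 22 down adjusted over the list alone. Absorptive enterocyte genes had a median log2 fold change of -2.41 and a camera adjusted p = 3.2e-16, and adjusted p = 0.27 with an estimated correlation. Over all genes, 1 of 24 tested cell cycle genes rose, 0 fell and 23 did not pass, or 10 up and 0 down adjusted over the list alone. Cell cycle genes had a median log2 fold change of 0.95 and a camera adjusted p = 8.4e-12, and adjusted p = 0.37 with an estimated correlation. The enteroendocrine list went both ways: 2 of 16 tested rose, 7 fell and 7 did not pass, or 2 up and 9 down adjusted over the list alone. Enteroendocrine genes had a median log2 fold change of -1.63 and a camera adjusted p = 2.6e-05, and adjusted p = 0.27 with an estimated correlation. No call by camera on a list fixed in advance, in any comparison, held with an estimated correlation. The correlation was estimated from the residuals of all 9 libraries, so the spread within the WT EphB2-negative pair enters comparisons without that group too. A lost call therefore does not show that the members did not shift. Pan-leukocyte genes summed to 72.1 and 68.7 CPM in the EphB2-positive libraries and to 136 and 1134 CPM in EphB2-negative replicates 1 and 2. None of the 11 members passed over all genes, against 0 up and 11 down adjusted over the list alone. Pan-leukocyte genes had a median log2 fold change of -6.58 and a camera adjusted p = 8.4e-06, and adjusted p = 0.38 with an estimated correlation. The median was -5.32 with genes at 0 reads set to their bound.

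Over all 11577 genes tested with edgeR's quasi-likelihood test, 76 rose and 437 fell, 513 in all. The count rested on single libraries: edgeR called 0 genes without WT EphB2-positive replicate 1 (with 2052 at an unadjusted p under 0.05), 1 without WT EphB2-positive replicate 2 and 5009 without WT EphB2-negative replicate 1. DESeq2 called 942 with all libraries. The count moved to 1 when the 4 WT libraries were fitted alone, 72 with the pan-leukocyte score as a covariate and 281 with voom and quality weights. It rose to 1248 (241 up and 1007 down) with a code in the names of the files as a block, which the labels do not tie to animals. None of the 15 printed genes that passed held without either WT EphB2-positive library. Without WT EphB2-negative replicate 1, 19 stem cell genes and 24 cell cycle genes rose, 11 pan-leukocyte genes fell, and the stem cell median was 1.90, against 0.77 without WT EphB2-negative replicate 2.

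The next comparison was the sort in KO. Cell cycle genes were higher in EphB2-positive cells (n = 3) than in EphB2-negative cells (n = 2), and 24 of 24 tested rose, 0 fell and 0 did not pass, or 24 up and 0 down adjusted over the list alone. Cell cycle genes had a median log2 fold change of 2.21 and a camera adjusted p = 3.3e-12, and adjusted p = 0.43 with an estimated correlation. Esco2, which joins sister chromatids in S phase, rose to 44.1 ± 2.901 against 2.55 ± 0.00865 CPM. Dctd, an enzyme of nucleotide synthesis, rose to 49.4 ± 8.72 against 1.91 ± 0.896 CPM, and Slc12a2, a chloride cotransporter of crypt cells, to 618 ± 15.9 against 39.9 ± 9.34 CPM. Cyclin E2, from Ccne2, rose with a ratio of 33.9 (counting interval 5.86 to 1361). Of the other rule genes that rose, Slfn9 stood at 104 ± 9.75 against 5.74 ± 3.59 CPM. Klhl23, Pla2g2a and Dtwd1 rested on 2 or 3 reads in EphB2-negative cells, with ratios of 25.6, 17.5 and 17.2 and counting intervals from 8.58 to 126, 5.81 to 86.5 and 4.57 to 146. Lower in EphB2-positive cells were the granzymes Gzmb, at least 295-fold, and Gzma, with a ratio of 3.51e-04 (counting interval 8.89e-06 to 0.00196), and the lymphocyte cytokine Il22, with a ratio of 3.79e-04 (counting interval 9.60e-06 to 0.00212). The neutrophil protein S100a9 was at least 193-fold lower, and the gelatinase Mmp9 at least 189.6-fold lower. Sla and Pla2g7 were at least 221-fold and 204-fold lower, and Mcpt1 fell with a ratio of 4.03e-04 (counting interval 1.02e-05 to 0.00225). Il22 has a near-identical copy, Iltifb, so its reads could be split or shared.

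Of the stem cell list in KO, 20 of 24 tested rose, 1 fell and 3 did not pass, or 20 up and 1 down adjusted over the list alone. Stem cell genes had a median log2 fold change of 2.56 and a camera adjusted p = 5.6e-08, and adjusted p = 0.43 with an estimated correlation. The absorptive list ran the other way: 0 of 25 tested rose, 24 fell and 1 did not pass, or 0 up and 24 down adjusted over the list alone. Absorptive enterocyte genes had a median log2 fold change of -4.69 and a camera adjusted p = 1.7e-18, and adjusted p = 0.43 with an estimated correlation. In the pan-leukocyte list 11 of 11 tested genes fell and 0 rose, the same as adjusted over the list alone. The sums were 92.4, 95.5 and 112 CPM in the EphB2-positive libraries and 1382 and 1036 CPM in the EphB2-negative libraries. Pan-leukocyte genes had a median log2 fold change of -9.02 and a camera adjusted p = 7.2e-04, and adjusted p = 0.43 with an estimated correlation. With edgeR, 3053 genes rose and 3375 fell. The count was 1018 with the pan-leukocyte score as a covariate, which ran from 0.895 to 1.13 in the EphB2-positive and from 6.38 to 6.65 in the EphB2-negative KO libraries. With it, 3 of the 17 named genes that passed kept their call. Of genes called in WT, 69 of 76 that rose and 402 of 437 that fell were called the same way in KO, where independent lists would share 20.04 and 127. The sort effects had r = 0.81 across genes, which are not independent replicates.

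The comparison of KO with WT in EphB2-positive cells bears on the question in the title. Transcripts of secreted antimicrobial proteins rose from low levels in WT: Reg3b (chromosome 6, 78370657 to 78373466, plus strand) stood at 25262 ± 1379 against 36.2 ± 15.1 CPM (n = 3 KO and 2 WT; log2 fold change 9.44 ± 1.69, adjusted p = 0.013). Reg3g (chromosome 6, 78466269 to 78468872, minus strand), like Reg3b a C-type lectin that acts on bacteria, stood at 14405 ± 1189 against 26.3 ± 6.69 CPM (log2 fold change 9.09 ± 1.24, adjusted p = 0.0037). Of genes that fell, Fabp2, the intestinal fatty acid binding protein, stood at 42.7 ± 12.4 against 329 ± 86.6 CPM and Hadha, an enzyme of mitochondrial beta-oxidation, at 245 ± 1.58 against 529.5 ± 53.5 CPM. Stem cell genes that passed went both ways, while the fixed markers Lgr5, Olfm4, Ascl2, Smoc2 and Axin2 stood lower in KO without passing. Of the fetal list, the Ly6a transcript alone passed. Ly6a (chromosome 15, 74994877 to 74998031, minus strand), which encodes the surface antigen Sca-1, had 0 reads in WT and 50.7 ± 32.1 CPM in KO, at least 68.7-fold higher (adjusted p = 0.016).

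In the list of antimicrobial and acute phase genes, 8 of 13 tested rose, 0 fell and 5 did not pass, or 8 up and 0 down adjusted over the list alone. The median log2 fold change was 5.11, also with genes at their bound, camera gave adjusted p = 8.3e-13, with adjusted p = 0.21 for an estimated correlation. Duoxa2, the maturation factor of an oxidase that makes hydrogen peroxide, stood at 157 ± 8.22 against 1.23 ± 0.352 CPM and Reg3a at 19.9 ± 1.88 against 1.97 ± 0.00598 CPM. Lcn2, which binds bacterial siderophores, rose from 3 reads over the WT libraries with a ratio of 79.6 (counting interval 27.01 to 388). The list summed to 44874, 40419 and 42782 CPM in the KO and 1682 and 1584 CPM in the WT libraries. Retnlb, a goblet cell protein that acts on bacteria, Lrg1 and Pla2g5 had 0 reads in WT and were at least 159-fold, 136-fold and 46.4-fold higher in KO. Of the Paneth list, 1 of 8 tested rose, 0 fell and 7 did not pass, or 1 up and 0 down adjusted over the list alone. Paneth cell genes had a median log2 fold change of 1.55 and a camera adjusted p = 0.0052, and adjusted p = 0.74 with an estimated correlation. Mmp7, which activates defensins, rose to 116 ± 39.4 against 6.3998 ± 0.0194 CPM. Lyz1, lysozyme, stood at 153 ± 77.1 against 24.6 ± 9.67 CPM without passing (adjusted p = 0.078). Of the goblet list, 1 of 13 tested rose, 0 fell and 12 did not pass, or 1 up and 0 down adjusted over the list alone. Goblet cell genes had a median log2 fold change of 0.58 and a camera adjusted p = 0.055, and adjusted p = 0.89 with an estimated correlation. Muc2 stood at 497 ± 179 against 123 ± 6.24 CPM (adjusted p = 0.20) and Zg16 at 14.3 ± 12.2 against 1.23 ± 1.04 CPM (adjusted p = 0.16).

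Of NF-κB targets, 6 of 22 tested rose, 1 fell and 15 did not pass, or 6 up and 1 down adjusted over the list alone. NF-κB targets had a median log2 fold change of 0.75 and a camera adjusted p = 0.0012, and adjusted p = 0.71 with an estimated correlation. Icam1, an adhesion molecule, rose to 48.3 ± 14.2 against 6.402 ± 1.41 CPM, Bcl3, a nuclear IκB protein, to 72.2 ± 9.94 against 24.9 ± 3.75 CPM, and Irf1 to 227 ± 40.4 against 119.6 ± 5.24 CPM. Tnf had 0 reads in WT and was at least 7.98-fold higher in KO. Nfkb2 and Tnfaip3, both induced by NF-κB, stood at 25.4 ± 2.07 against 15.3 ± 4.92 CPM (adjusted p = 0.16) and 41.7 ± 5.33 against 12.6 ± 10.8 CPM (adjusted p = 0.40). Cxcl1, with 17 reads in KO and 3 in WT, was too low to be tested. Of the interferon list, 5 of 19 tested rose, 0 fell and 14 did not pass, or 5 up and 0 down adjusted over the list alone. Interferon response genes had a median log2 fold change of 0.71 and a camera adjusted p = 0.0034, and adjusted p = 0.81 with an estimated correlation. Irgm1, an interferon-induced GTPase, rose by 2.02 ± 0.23 on the log2 scale. The GTPases Tgtp1 and Tgtp2, near-identical copies between which counting could split reads, rose from 1 read each with ratios of 336 (counting interval 59.9 to 13286) and 289 (interval 51.5 to 11433). Socs3, a feedback inhibitor of cytokine signalling on the list of immediate early genes, rose to 151 ± 13.2 against 12.3 ± 6.999 CPM. On that list 1 of 13 tested rose, 1 fell and 11 did not pass, or 1 up and 1 down adjusted over the list alone. Immediate early genes had a camera adjusted p = 0.64, and adjusted p = 0.94 with an estimated correlation. Their median of -0.56 and mean of -0.08 lay below 0 where camera's direction was up.

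Of the fetal list, 1 of 14 tested rose, 0 fell and 13 did not pass, or 1 up and 0 down adjusted over the list alone. The median log2 fold change was 0.26, or 0.00 with genes at 0 reads set to their bound, and the mean 1.01 (camera adjusted p = 0.35, adjusted p = 0.94 with an estimated correlation). Spp1, Gja1 and Clu, fetal markers fixed in advance, were near or at 0: Spp1 had 0 reads in each EphB2-positive library, Gja1 had 6 reads in KO and 6 in WT and Clu 0 reads in KO and 4 in WT. Clu did not pass (adjusted p = 0.22), and Spp1 and Gja1 were too low to be tested. Plaur stood at 4.33 ± 1.59 against 0.247 ± 0.349 CPM, a ratio of 16.9 (counting interval 2.74 to 694), and did not pass (adjusted p = 0.070), nor did Il1rn, with 4 reads in KO and 0 in WT (adjusted p = 0.14). Krt7 stood at 112 ± 8.703 against 175 ± 29.4 CPM (adjusted p = 0.20) and Anxa1 at 13.3 ± 2.94 against 9.36 ± 1.42 CPM (adjusted p = 0.47). Of the growth and imprinted fetal list, 1 of 12 tested rose, 0 fell and 11 did not pass, or 0 up and 0 down adjusted over the list alone. Growth and imprinted genes had a median log2 fold change of -0.33 and a camera adjusted p = 0.48, and adjusted p = 0.81 with an estimated correlation. The RNA-binding protein gene Igf2bp1 stood at 38.8 ± 6.83 against 21.9 ± 6.68 CPM. Of the stem cell list, 4 of 24 tested rose, 3 fell and 17 did not pass, or 4 up and 4 down adjusted over the list alone. Stem cell genes had a median log2 fold change of -0.31 and a camera adjusted p = 0.54, and adjusted p = 0.94 with an estimated correlation. Cd44 rose to 148 ± 11.98 against 50.9 ± 9.24 CPM and Sp5 to 16.95 ± 3.98 against 3.69 ± 0.337 CPM. Tert, the telomerase catalytic subunit, and Rnf43, which removes Wnt receptors, had log2 fold changes of -3.46 ± 0.29 and -1.16 ± 0.25. Lgr5, a receptor for R-spondins on crypt base stem cells, stood at 63.7 ± 7.35 against 103 ± 23.01 CPM (adjusted p = 0.30) and Olfm4 at 1605 ± 493 against 3278 ± 140.4 CPM (adjusted p = 0.28). Ascl2 stood at 17.7 ± 3.55 against 39.6 ± 16.9 CPM (adjusted p = 0.20), Smoc2 at 116 ± 20.8 against 159.98 ± 6.48 CPM (adjusted p = 0.62) and Axin2 at 69.6 ± 10.4 against 168 ± 8.19 CPM (adjusted p = 0.067). Each of these fixed markers was lower in every KO than in every WT EphB2-positive library. For a single gene, 20% of splits of these libraries give no overlap. The stem cell list summed to 3737, 3518 and 4595 CPM in KO and to 6627 and 5929 CPM in WT.

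Of Wnt targets, 3 of 13 tested rose, 1 fell and 9 did not pass, or 3 up and 2 down adjusted over the list alone. Wnt targets had a camera adjusted p = 0.91, and adjusted p = 0.94 with an estimated correlation. The median was -0.27 and the mean -0.23, where camera's direction was up. For the Notch pathway, 0 of 10 tested rose, 3 fell and 7 did not pass, or 0 up and 6 down adjusted over the list alone. Notch genes had a median log2 fold change of -0.74 and a camera adjusted p = 0.0073, and adjusted p = 0.21 with an estimated correlation. The receptor gene Notch1 fell to 49.3 ± 5.999 against 106 ± 14.6 CPM and its target Hes1 to 52.99 ± 3.91 against 96.3 ± 11.1 CPM. Lfng, a glycosyltransferase that modifies Notch, fell to 5.76 ± 1.53 against 30.99 ± 13.8 CPM. Of cell cycle genes, 1 of 24 tested rose, 0 fell and 23 did not pass, or 0 up and 0 down adjusted over the list alone. Cell cycle genes had a median log2 fold change of 0.05 and a camera adjusted p = 0.59, and adjusted p = 0.94 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, stood at 213 ± 27.03 against 114 ± 1.74 CPM, and Mki67, a marker of cycling cells, at 609 ± 28.4 against 631 ± 70.5 CPM (adjusted p = 0.95). Of PRC2 subunits, 1 of 11 tested rose, 1 fell and 9 did not pass, or 1 up and 1 down adjusted over the list alone. PRC2 subunits had a camera adjusted p = 0.92, and adjusted p = 0.94 with an estimated correlation. The median was -0.07 and the mean -0.13, where camera's direction was up. Suz12 and Phf19 had log2 fold changes of 0.68 ± 0.14 and -1.89 ± 0.54, and Ezh2, the methyltransferase, stood at 119 ± 4.04 against 140.1 ± 11.2 CPM (adjusted p = 0.52).

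Of absorptive enterocyte genes, 1 of 25 tested rose, 9 fell and 15 did not pass, or 1 up and 11 down adjusted over the list alone. Their median log2 fold change was -1.48, or -1.22 with genes at 0 reads set to their bound (camera adjusted p = 7.6e-06, adjusted p = 0.73 with an estimated correlation). The brush border peptidase Anpep fell to 113 ± 44.3 against 736 ± 385 CPM and Fabp1 to 7.78 ± 1.65 against 72.4 ± 44.8 CPM. Dgat1, which makes triglyceride, fell to 69.1 ± 5.88 against 149 ± 31.8 CPM and Alpi, intestinal alkaline phosphatase, to 17.4 ± 1.89 against 85.96 ± 39.6 CPM. Among suckling enterocyte genes, 0 of 10 tested rose, 5 fell and 5 did not pass, or 0 up and 7 down adjusted over the list alone. Suckling enterocyte genes had a median log2 fold change of -1.98 and a camera adjusted p = 1.1e-05, and adjusted p = 0.60 with an estimated correlation. Amn, part of the receptor for intrinsic factor, fell to 18.7 ± 1.597 against 95.5 ± 7.95 CPM, and Cps1, of the urea cycle, to 3286 ± 557 against 6930.3 ± 879 CPM. Prdm1 and Fcgrt, which carries milk antibodies, had log2 fold changes of -1.38 ± 0.30 and -2.19 ± 0.48. Lactase, from Lct, stood at 1.37 ± 0.636 against 17.3 ± 15.4 CPM and sucrase-isomaltase, from Sis, at 2.86 ± 0.415 against 8.61 ± 5.89 CPM, without passing (adjusted p = 0.19 and 0.43). Of the PPAR and fatty acid oxidation list, 1 of 15 tested rose, 8 fell and 6 did not pass, or 1 up and 12 down adjusted over the list alone. Its median was -1.43, or -1.11 with bounds (camera adjusted p = 2.9e-09, adjusted p = 0.21 with an estimated correlation). Acaa2, a thiolase of the same pathway as Hadha, stood at 132 ± 17.8 against 588 ± 64.8 CPM. For retinoic acid, 0 of 12 tested rose, 4 fell and 8 did not pass, or 0 up and 9 down adjusted over the list alone. Retinoic acid genes had a median log2 fold change of -1.29 and a camera adjusted p = 5.3e-04, and adjusted p = 0.21 with an estimated correlation. Aldh1a1, a retinal dehydrogenase, stood at 19.6 ± 8.69 against 69.7 ± 8.22 CPM. The receptor gene Rara stood at 35.4 ± 5.07 against 64.2 ± 3.63 CPM and Lrat, which esterifies retinol, at 0.673 ± 0.79 against 6.399 ± 0.677 CPM. Rarb had 1 read in KO and 0 in WT.

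Of enteroendocrine genes, 1 of 16 tested rose, 5 fell and 10 did not pass, or 1 up and 6 down adjusted over the list alone. Enteroendocrine genes had a median log2 fold change of -0.75 and a camera adjusted p = 0.0057, and adjusted p = 0.71 with an estimated correlation. The hormone genes Pyy, Gcg and Gip had log2 fold changes of -2.65 ± 0.27, -1.63 ± 0.23 and -2.73 ± 0.48. Chga stood at 48.3 ± 7.25 against 43.8 ± 21.4 CPM (adjusted p = 0.91). The tuft cell marker Dclk1 had 3 reads in KO and 24 in WT, 22 of them in WT EphB2-positive replicate 1, and was not tested. Of cholesterol synthesis genes, 7 of 16 tested rose, 0 fell and 9 did not pass, or 11 up and 0 down adjusted over the list alone. Cholesterol synthesis genes had a median log2 fold change of 0.79 and a camera adjusted p = 1.7e-06, and adjusted p = 0.69 with an estimated correlation. Idi1 stood at 219 ± 27.4 against 108 ± 3.501 CPM, Lss at 78.5 ± 3.31 against 33.5 ± 6.37 CPM and Fdps at 179.5 ± 17.6 against 90.3 ± 5.496 CPM. Genes with 0 to 3 reads over the KO libraries included Lect2 (chromosome 13, 56542464 to 56548502, minus strand), a secreted protein known from liver, at least 67.3-fold lower, and Mme, the peptidase neprilysin, at least 33.7-fold lower. Sfrp5, a secreted Wnt antagonist, fell with a ratio of 0.00333 (counting interval 8.40e-05 to 0.0188), and Ptprt and Hsd3b3 fell with ratios of 0.0074 (0.00152 to 0.0218) and 0.0151 (0.0018 to 0.0561). Nr2e3, a nuclear receptor gene, fell to 2.83 ± 2.76 against 129 ± 23.4 CPM and Cyp2w1, a cytochrome P450 known from fetal gut and colon tumours, to 1.71 ± 0.856 against 60.3 ± 6.101 CPM. Pan-leukocyte genes summed to 92.4, 95.5 and 112 CPM in KO and 72.1 and 68.7 CPM in WT. Of these, 0 of 11 tested rose, 0 fell and 11 did not pass, the same as adjusted over the list alone. Pan-leukocyte genes had a camera adjusted p = 0.89, and adjusted p = 0.94 with an estimated correlation. Of myeloid genes, 1 of 13 tested rose, 0 fell and 12 did not pass, or 1 up and 0 down adjusted over the list alone. Myeloid genes had a camera adjusted p = 0.64, and adjusted p = 0.94 with an estimated correlation. The riser was Cd14, a receptor for bacterial lipopolysaccharide, at 20.7 ± 2.14 against 4.43 ± 0.683 CPM.

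**Figure D2:**
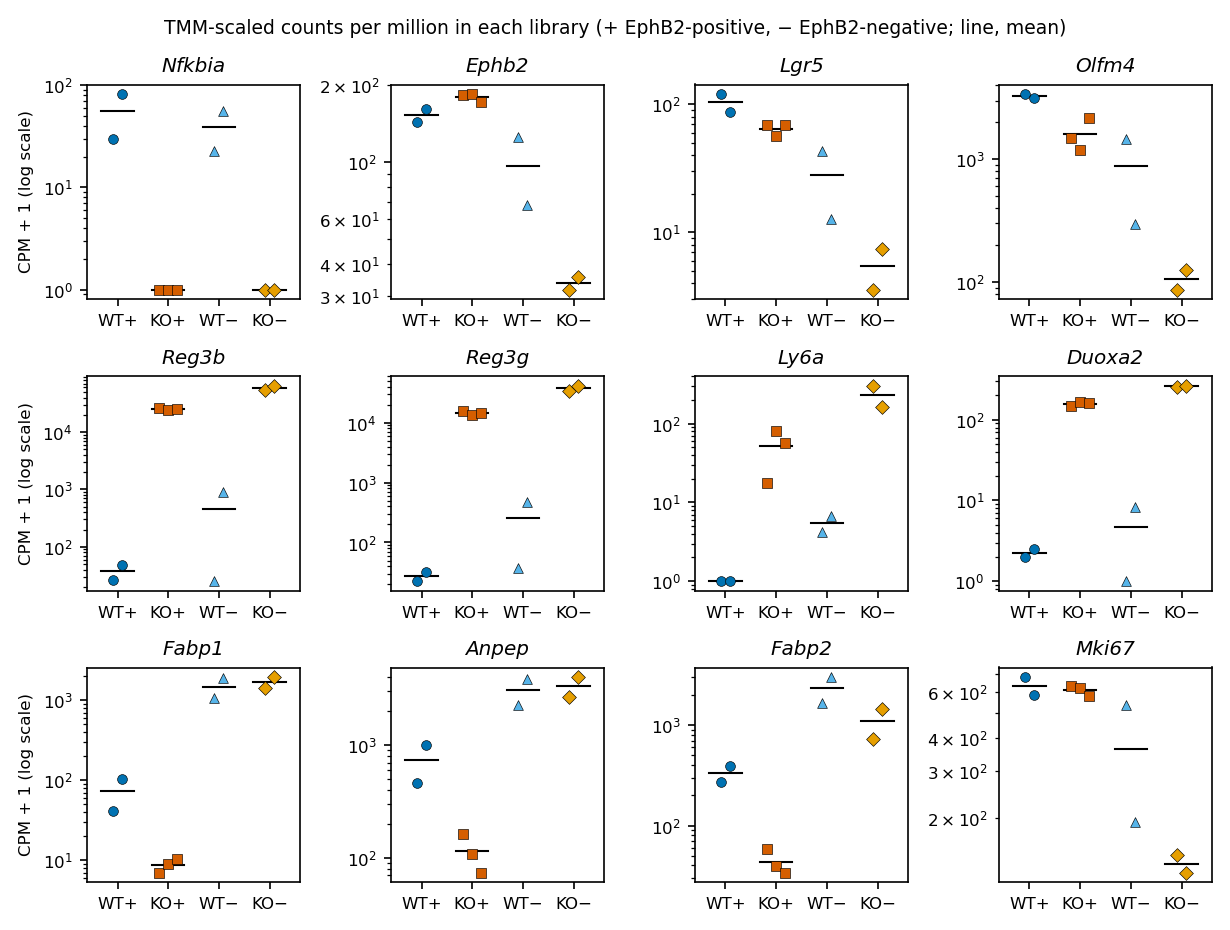
CPM + 1 on a log axis for 12 genes in each of the 9 libraries, grouped as WT and KO, EphB2-positive (+) and EphB2-negative (−), with a line at the group mean. Nfkbia is at 0 in all 5 KO libraries, and Reg3b lies at 25262 CPM on average in the KO EphB2-positive libraries against 36.2 CPM in the WT EphB2-positive libraries.

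Over all genes tested with edgeR, 812 rose and 934 fell in KO EphB2-positive cells. More genes rose than fell with DESeq2's size factors (914 and 861) and with DESeq2 (794 and 637). Of the 167 genes taken by the rule, 82 passed. Of the 167, 58 that passed and 26 that did not are printed here. Leaving out WT EphB2-positive replicate 1, WT EphB2-positive replicate 2 or KO EphB2-positive replicate 1, 2 or 3 left 568, 573, 1034, 791 and 980 calls and kept 39, 37, 51, 44 and 48 of these 58 genes. Leaving WT EphB2-negative replicate 1 out of the fit gave 3449 (1730 up and 1719 down) and kept 54. The count moved to 3734 with the 5 libraries fitted alone, 3353 with the pan-leukocyte score, 3141 with a crypt score chosen after seeing the data and 3470 with voom and quality weights.

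In EphB2-negative cells, 13 of 13 tested antimicrobial genes and 14 of 22 NF-κB targets rose in KO (n = 2 and 2). Of stem cell genes 13 of 24 fell and 2 rose, and of cell cycle genes 15 of 24 fell. The calls by camera on these 4 lists were lost with an estimated correlation (adjusted p = 0.26, 0.42, 0.52 and 0.57). Saa3, an acute phase protein, rose from 3 reads over the WT libraries to 662 ± 506 CPM, a ratio of 941 (counting interval 321 to 4565). Nos2, which makes nitric oxide, stood at 349.8 ± 192 against 1.92 ± 2.07 CPM, Duoxa2 at 257 ± 7.25 against 3.63 ± 5.13 CPM and Reg3a at 47.5 ± 11.1 against 2.58 ± 0.226 CPM. Krt20, a keratin of differentiated enterocytes, rose to 1375 ± 230.04 against 148 ± 126 CPM (log2 fold change 3.21 ± 0.54, adjusted p = 0.0053). Olfm4 fell to 105 ± 26.7 against 872 ± 817 CPM (log2 fold change -3.06 ± 0.70, adjusted p = 0.017). The stem cell list summed to 3221 CPM in WT EphB2-negative replicate 1 and 1064 CPM in replicate 2, against 489 and 566 CPM in KO. The WT libraries differed more from each other than replicate 2 did from KO.

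Of antimicrobial genes, 13 of 13 tested rose, 0 fell and 0 did not pass, the same as adjusted over the list alone. Antimicrobial genes had a median log2 fold change of 7.04 and a camera adjusted p = 1.9e-18, and adjusted p = 0.26 with an estimated correlation. Lcn2 rose from 3 reads with a ratio of 392 (counting interval 134 to 1903), and Saa1, Ly6f, Prss27 and Duox1 had 0 reads in WT and were at least 120.3-fold, 36.7-fold, 28.5-fold and 25.3-fold higher. Saa1 has close copies, so its count is uncertain. For NF-κB targets, 14 of 22 tested rose, 0 fell and 8 did not pass, or 17 up and 0 down adjusted over the list alone. NF-κB targets had a median log2 fold change of 1.69 and a camera adjusted p = 6.7e-09, and adjusted p = 0.42 with an estimated correlation. Bcl3, Irf1, Tnip1, Icam1 and Nfkb2 rose by 1.80 ± 0.20, 1.52 ± 0.19, 1.46 ± 0.19, 2.38 ± 0.39 and 1.55 ± 0.32 on the log2 scale. Tnfaip3 stood at 330.2 ± 86.9 against 73.4 ± 96.05 CPM without passing (adjusted p = 0.16), and Cxcl1, with 22 reads in KO and 7 in WT, was not tested. Socs3 rose to 423 ± 11.2 against 24.8 ± 16.97 CPM. On the immediate early list that holds Socs3, 1 of 13 tested rose, 0 fell and 12 did not pass, or 1 up and 0 down adjusted over the list alone. Immediate early genes had a median log2 fold change of 0.60 and a camera adjusted p = 0.14, and adjusted p = 0.76 with an estimated correlation. They summed to 657 and 4122 CPM in WT replicates 1 and 2 and to 3360 and 2369 CPM in KO, again between the WT libraries. Of interferon genes, 8 of 19 tested rose, 0 fell and 11 did not pass, or 10 up and 0 down adjusted over the list alone. Interferon response genes had a median log2 fold change of 1.38 and a camera adjusted p = 3.5e-05, and adjusted p = 0.52 with an estimated correlation. Isg15 stood at 67.98 ± 0.682 against 10.3 ± 7.399 CPM and Irgm1 at 239 ± 51.4 against 51.1 ± 7.09 CPM. Of the fetal list, 7 of 14 tested rose, 0 fell and 7 did not pass, or 8 up and 0 down adjusted over the list alone. Fetal list genes had a median log2 fold change of 1.53 and a camera adjusted p = 0.0028, and adjusted p = 0.52 with an estimated correlation. Markers of other cells were also higher in the KO libraries: fibroblast and muscle genes summed to 26.8 and 171 CPM in WT replicates 1 and 2 and to 408 and 336 CPM in KO, and endothelial genes to 11.7 and 54.8 CPM in WT and 88.8 and 85.7 CPM in KO. Of the fibroblast and muscle list, 1 of 9 tested rose, 0 fell and 8 did not pass (camera adjusted p = 0.029, adjusted p = 0.52 with an estimated correlation), and myeloid genes are given below. Ly6a stood at 231 ± 100.1 against 4.502 ± 1.85 CPM and Il1rn, an antagonist of interleukin 1, at 25.9 ± 0.539 against 0.954 ± 0.704 CPM. Ecm1 stood at 36.1 ± 2.38 against 3.32 ± 1.47 CPM and Anxa1 at 23.9 ± 13.9 against 7.56 ± 2.31 CPM. Of the fetal markers fixed in advance, Gja1 had 7 reads in KO and 0 in WT and Spp1 21 reads in KO and 14 in WT, too low to be tested. Clu stood at 5.74 ± 2.69 against 5.66 ± 0.897 CPM (adjusted p = 0.99).

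Of stem cell genes, 2 of 24 tested rose, 13 fell and 9 did not pass, or 2 up and 17 down adjusted over the list alone. Stem cell genes had a median log2 fold change of -1.76 and a camera adjusted p = 1.0e-04, and adjusted p = 0.52 with an estimated correlation. Lgr5 fell to 4.46 ± 2.69 against 26.8 ± 21.5 CPM, Sox9 to 4.47 ± 0.918 against 59.5 ± 31.4 CPM and Hopx to 16.9 ± 3.22 against 68.4 ± 20.8 CPM. Slc12a2 fell to 39.9 ± 9.34 against 295 ± 208 CPM and Tert to 9.57 ± 0.87 against 37.1 ± 3.12 CPM. Ascl2, Smoc2 and Axin2 did not pass (adjusted p = 0.062, 0.061 and 0.16). Of Wnt targets, 1 of 13 tested rose, 7 fell and 5 did not pass, or 1 up and 8 down adjusted over the list alone. Wnt targets had a median log2 fold change of -1.22 and a camera adjusted p = 0.017, and adjusted p = 0.52 with an estimated correlation. Rnf43 and Cd44 had log2 fold changes of -1.57 ± 0.32 and 0.71 ± 0.19. Of cell cycle genes, 0 of 24 tested rose, 15 fell and 9 did not pass, or 0 up and 17 down adjusted over the list alone. Cell cycle genes had a median log2 fold change of -1.13 and a camera adjusted p = 1.6e-05, and adjusted p = 0.57 with an estimated correlation. Mcm6, Mcm2, Top2a and Mki67 had log2 fold changes of -2.01 ± 0.31, -1.53 ± 0.30, -1.47 ± 0.29 and -1.45 ± 0.39. Of the growth and imprinted fetal list, 0 of 12 tested rose, 6 fell and 6 did not pass, or 0 up and 6 down adjusted over the list alone. Growth and imprinted genes had a median log2 fold change of -1.15 and a camera adjusted p = 0.0060, and adjusted p = 0.36 with an estimated correlation. Afp fell to 15.95 ± 1.75 against 265 ± 133 CPM, the imprinted gene Grb10 to 12.5 ± 4.104 against 51.1 ± 6.53 CPM and Igf2bp3 to 109 ± 12.6 against 191 ± 12.7 CPM. Of PRC2 subunits, 1 of 11 tested rose, 4 fell and 6 did not pass, or 1 up and 7 down adjusted over the list alone. PRC2 subunits had a median log2 fold change of -0.62 and a camera adjusted p = 0.14, and adjusted p = 0.52 with an estimated correlation. Eed, Rbbp4 and Ezh2 stood at -1.24 ± 0.22, -1.04 ± 0.22 and -0.83 ± 0.26 on the log2 scale. Of the Notch list, 0 of 10 tested rose, 3 fell and 7 did not pass, the same as adjusted over the list alone. Notch genes had a median log2 fold change of -0.52 and a camera adjusted p = 0.26, and adjusted p = 0.52 with an estimated correlation. Without WT EphB2-negative replicate 1, the stem cell and cell cycle medians were -1.03 and -0.46 (camera adjusted p = 0.0063 and 0.019).

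Of absorptive enterocyte genes, 7 of 25 tested rose, 0 fell and 18 did not pass in EphB2-negative cells, or 7 up and 0 down adjusted over the list alone. Absorptive enterocyte genes had a median log2 fold change of 0.68 and a camera adjusted p = 0.0016, and adjusted p = 0.58 with an estimated correlation. The maltase-glucoamylase gene Mgam, the glucose transporter gene Slc5a1 and Dgat1 rose to 1461 ± 227 against 435 ± 60.4 CPM, 1315 ± 402 against 269 ± 134 CPM and 652 ± 101 against 222 ± 9.16 CPM. Alpi, Lct and Sis did not pass, at 1032 ± 346 against 668 ± 311 CPM, 128 ± 97.96 against 656 ± 622 CPM and 43.05 ± 23.8 against 124 ± 117 CPM (adjusted p = 0.24, 0.094 and 0.16). The list summed to 16206 and 37823 CPM in WT replicates 1 and 2 and to 30622 and 41332 CPM in KO. Of the suckling list, 1 of 10 tested rose, 3 fell and 6 did not pass, or 1 up and 3 down adjusted over the list alone. Suckling enterocyte genes had a median log2 fold change of -0.50 and a camera adjusted p = 0.26, and adjusted p = 0.76 with an estimated correlation. Cps1, Cubn and Nox4 fell to 1149.7 ± 117 against 4772 ± 2018 CPM, 5.74 ± 2.69 against 91.5 ± 84.8 CPM and 1.28 ± 1.81 against 27.3 ± 14.7 CPM. Clec2h rose to 1492 ± 367 against 177 ± 172 CPM. Of the PPAR list, 3 of 15 tested rose, 6 fell and 6 did not pass, or 3 up and 7 down adjusted over the list alone. Fatty acid oxidation genes had a median log2 fold change of -0.43 and a camera adjusted p = 0.18, and adjusted p = 0.66 with an estimated correlation. Acadl stood at 1046 ± 146 against 499 ± 26.6 CPM. Of the cholesterol list, 4 of 16 tested rose, 0 fell and 12 did not pass, or 4 up and 0 down adjusted over the list alone. Cholesterol synthesis genes had a median log2 fold change of 0.51 and a camera adjusted p = 0.015, and adjusted p = 0.60 with an estimated correlation. For retinoic acid, 0 of 12 tested rose, 5 fell and 7 did not pass, or 0 up and 5 down adjusted over the list alone. Retinoic acid genes had a median log2 fold change of -0.54 and a camera adjusted p = 0.028, and adjusted p = 0.52 with an estimated correlation. Aldh1a1 and Retsat, retinol saturase, stood at 32.2 ± 8.47 against 194 ± 32.3 CPM and 42.8 ± 3.47 against 152 ± 29.9 CPM. Rarb had 7 reads in KO and 3 in WT. Of goblet genes, 2 of 13 tested rose, 0 fell and 11 did not pass, or 2 up and 0 down adjusted over the list alone. Goblet cell genes had a median log2 fold change of -1.06 and a camera adjusted p = 0.64, and adjusted p = 0.87 with an estimated correlation. The risers Zg16 and Retnlb stood at 365 ± 299 against 25.7 ± 6.25 CPM and 39.9 ± 19.3 against 1.21 ± 1.71 CPM, and Muc2, which did not pass, at 833 ± 182 against 1399.7 ± 1644 CPM (adjusted p = 0.57). Without WT EphB2-negative replicate 1, the absorptive median was 0.38 with 3 members down (camera adjusted p = 0.038), the suckling list passed with a median of -1.04 (camera adjusted p = 0.023), and the cholesterol list did not (camera adjusted p = 0.17). Goblet genes summed to 3370 and 26154 CPM in WT replicates 1 and 2 and to 5624 and 7273 CPM in KO. The KO sums lay between those of the WT libraries, so the direction turned on which WT library was used. Muc2 passed in opposite directions with either WT library left out: its log2 fold change was -1.62 (adjusted p = 0.046) without WT EphB2-negative replicate 1 and 1.81 (adjusted p = 0.036) without WT EphB2-negative replicate 2.

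The hormone genes Gcg and Gip fell in EphB2-negative cells, to 5.75 ± 4.53 against 53.5 ± 1.78 CPM and 148 ± 47.4 against 578 ± 19.04 CPM. In the enteroendocrine list 0 of 16 tested rose, 3 fell and 13 did not pass, or 0 up and 9 down adjusted over the list alone. Enteroendocrine genes had a median log2 fold change of -1.23 and a camera adjusted p = 0.0057, and adjusted p = 0.52 with an estimated correlation. For Paneth genes, 1 of 8 tested rose, 0 fell and 7 did not pass, or 0 up and 0 down adjusted over the list alone. Paneth cell genes had a median log2 fold change of -1.78 and a camera adjusted p = 0.58, and adjusted p = 0.87 with an estimated correlation. Lyz1 stood at 33.5 ± 22.9 against 33.05 ± 30.6 CPM (adjusted p = 0.98) and the hormone granule gene Chga at 511 ± 193 against 1030.1 ± 718 CPM (adjusted p = 0.18), and Dclk1 had 0 reads in KO and 3 in WT. Paneth genes summed to 136 and 4146 CPM in WT replicates 1 and 2 and to 407 and 268 CPM in KO. Here too the KO sums lay between those of the WT libraries. Car4, a carbonic anhydrase of colon, rose from 1 read with a ratio of 956 (counting interval 171 to 37830.1). Of the extremes that fell, Lect2, Ces1c, Afm and Sfrp5 had 0 reads in KO and were at least 67.2-fold, 50.8-fold, 17.01-fold and 16.4-fold lower. Over the KO libraries, 1 read of Nr2e3, 1 of Cyp4a10 and 2 of Cyp2w1 were left. Nr2e3 fell with a ratio of 0.00168 (counting interval 4.26e-05 to 0.00941), Cyp4a10 with a ratio of 0.00999 (counting interval 2.51e-04 to 0.0566) and Cyp2w1 with a ratio of 0.0128 (counting interval 0.00154 to 0.0469). Il17f, a lymphocyte cytokine gene, had 0 reads in WT and 116 ± 116 CPM in KO, at least 165-fold higher. Of myeloid genes, 6 of 13 tested rose, 0 fell and 7 did not pass, or 7 up and 0 down adjusted over the list alone. Myeloid genes had a median log2 fold change of 3.03 and a camera adjusted p = 1.8e-04, and adjusted p = 0.52 with an estimated correlation. Itgam, a leukocyte integrin, stood at 63.5 ± 29.1 against 10.3 ± 9.39 CPM, Cd14 at 19.5 ± 3.09 against 3.09 ± 1.79 CPM. The neutrophil granule genes Ltf and Ngp rose, Ltf to 28.05 ± 23.4 against 2.62 ± 1.77 CPM and Ngp to 21.03 ± 17.98 against 0.726 ± 1.03 CPM, a ratio of 29.9 (counting interval 9.79 to 149). Pan-leukocyte genes summed to 136 and 1134 CPM in WT replicates 1 and 2 and to 1382 and 1036 CPM in KO. Of these, 0 of 11 tested rose, 0 fell and 11 did not pass, the same as adjusted over the list alone. Pan-leukocyte genes had a median log2 fold change of 1.68 and a camera adjusted p = 0.056, and adjusted p = 0.66 with an estimated correlation. Pancreas acinar genes summed to 1831 and 215 CPM in WT and 42.997 and 137 CPM in KO. Of these genes, 0 of 8 tested rose, 3 fell and 5 did not pass, the same as adjusted over the list alone. Acinar genes had a median log2 fold change of -2.99 and a camera adjusted p = 0.015, and adjusted p = 0.57 with an estimated correlation, and camera adjusted p = 0.17 without WT EphB2-negative replicate 1.

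**Figure D3:**
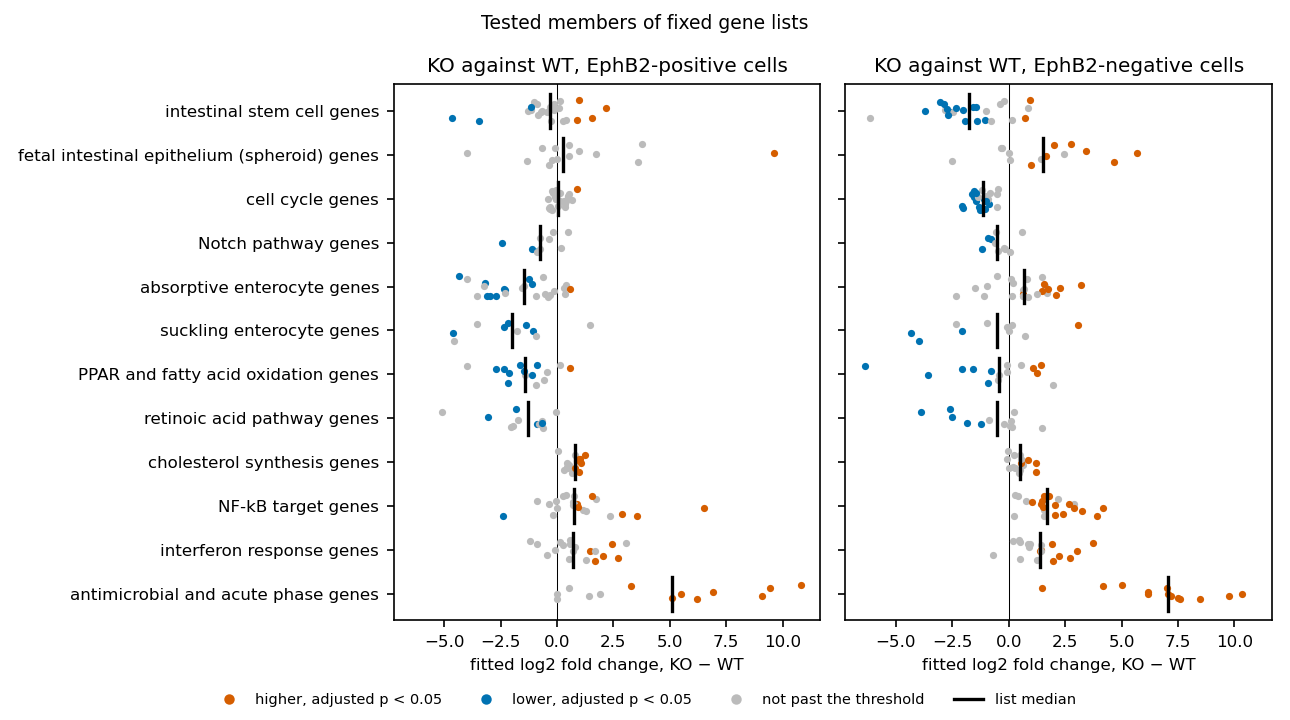
Fitted log2 fold changes (KO minus WT) of the tested members of 12 fixed gene lists in EphB2-positive and EphB2-negative cells, each point a gene, coloured by whether its adjusted p was under 0.05, with a line at the list median. All 13 antimicrobial genes rose in EphB2-negative cells and 8 of 13 rose in EphB2-positive cells; points of genes with 0 reads in a group are fitted values, not bounds.

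Over all genes tested with edgeR, 1586 rose and 1870 fell in KO EphB2-negative cells, and 105 of the 168 genes taken by the rule passed. Of the 168, 69 that passed and 16 that did not are printed here. Without WT EphB2-negative replicate 1 the count was 3522, of which 2619 were shared, and 9 of 13 antimicrobial genes rose. Leaving out WT EphB2-negative replicate 2 or KO EphB2-negative replicate 1 or 2 gave 5834, 1727 and 1096 calls. The count was 149 (116 up and 33 down) with the 4 libraries fitted alone, 1779 with the crypt score and 1516 with voom and quality weights. DESeq2 called 1434 up and 1067 down, 57.3% up against 45.9%.

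The last comparison tested whether the genotype effect differed between the sorts, as the effect in EphB2-positive minus that in EphB2-negative cells. By the crypt score, the sorts lay further apart in KO than in WT, so a difference can also come from the sort. Ccnd2, which encodes cyclin D2, had the difference 2.21 ± 0.26, and Ipo7, a nuclear import receptor, 2.04 ± 0.23 on the log2 scale. Mat2a, which makes S-adenosylmethionine, had 2.26 ± 0.28, and Usp14, a deubiquitinase, 1.92 ± 0.24. In the other direction were Dgat1 with -2.66 ± 0.26, Naprt, of NAD synthesis, with -2.56 ± 0.20, Slc34a2, a phosphate transporter gene, with -4.56 ± 0.47, Smim24 with -2.65 ± 0.25 and Clcn2, a chloride channel gene, with -2.53 ± 0.28. Adjusted p lay between 0.0025 and 0.0069 for these 9 genes, taken in each direction by p-value, and each held in the 17 other settings run. Of all 36 printed genes that passed for the difference, 10 held in each of these settings. Dgat1 fell in KO EphB2-positive cells and rose in KO EphB2-negative cells. Absorptive genes had a median difference of -2.26, with 10 of 25 below 0 past the threshold and 19 adjusted over the list alone (camera adjusted p = 8.2e-14, adjusted p = 0.61 with an estimated correlation). Cell cycle genes had a median of 1.29, with 5 of 24 above 0 and 16 adjusted over the list alone (camera adjusted p = 8.2e-07, adjusted p = 0.61 with an estimated correlation). Stem cell genes had a median of 1.39 (camera adjusted p = 6.2e-04, adjusted p = 0.61 with an estimated correlation). For antimicrobial genes the difference did not pass, with a median of -0.95 and 0 of 13 members past the threshold (camera adjusted p = 0.45), which does not show that the effects were alike. The fetal list gave -0.92 (camera adjusted p = 0.28). Without WT EphB2-negative replicate 1 the medians were 0.75 for stem cell and 0.48 for cell cycle genes (camera adjusted p = 0.038 and 0.0025), and 3 antimicrobial genes lay above and 1 below 0 past the threshold.

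With edgeR, 757 genes had a positive and 673 a negative difference, against 693 and 746 with DESeq2's size factors and 632 and 680 with DESeq2. Of genes that rose in KO EphB2-positive cells, 413 also rose in EphB2-negative cells where independent lists would share 111. Of those that fell, 337 also fell (151 by chance), and 55 and 66 were called in opposite directions. The genotype effects had r = 0.47 across genes. The comparisons share no library, but codes in the names of the files recur in both sorts, so the comparisons are not known to be independent, as the chance counts assume. The count of differing genes was 251 without WT EphB2-positive replicate 1, 32 without WT EphB2-positive replicate 2, 2339 without WT EphB2-negative replicate 1 and 3996 without WT EphB2-negative replicate 2. It was 538, 404 and 602 without KO EphB2-positive replicates 1, 2 and 3, and 500 and 40 without KO EphB2-negative replicates 1 and 2.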

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

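The tests of explanations below, on WT EphB2-negative replicate 1, on antimicrobial genes, on absorptive genes and on fatty acid oxidation genes, were chosen only after the result was seen; those of the difference between the sorts were planned. For 54 of 242 genes taken by the rule and 12 of 33 lists, the genotype effect differed between the sorts by edgeR's test of the difference or by camera. The 36 of 123 printed genes that differed follow. Values are the log2 effect in EphB2-positive minus that in EphB2-negative cells. A negative difference was found for Alpi -2.92 ± 0.57, Dgat1 -2.66 ± 0.26, Fabp1 -3.37 ± 0.63, Anpep -2.82 ± 0.63, Amn -2.29 ± 0.26, Mgam -1.17 ± 0.24, Slc5a1 -2.00 ± 0.44, Krt20 -2.80 ± 0.73, Slc34a2 -4.56 ± 0.47 and Clcn2 -2.53 ± 0.28. Others below 0 were Tert -1.52 ± 0.43, Notch1 -0.94 ± 0.25, Pyy -1.85 ± 0.40, Acaa2 -1.23 ± 0.26, Tnip1 -1.50 ± 0.25, Itgam -3.38 ± 0.87, Naprt -2.56 ± 0.20, Smim24 -2.65 ± 0.25 and Prdm1 -1.50 ± 0.43. A positive difference was found for Ephb2 1.80 ± 0.35, Sox9 3.06 ± 0.58, Hopx 1.88 ± 0.36, Slc12a2 2.77 ± 0.59, Ccnd2 2.21 ± 0.26, Rrm2 1.39 ± 0.40, Mcm6 1.66 ± 0.40 and Top2a 1.87 ± 0.39. Further genes above 0 were Mmp7 2.78 ± 0.63, Suz12 0.74 ± 0.21, Idi1 1.10 ± 0.22, Grb10 1.66 ± 0.31, Retsat 1.16 ± 0.28, Eed 1.55 ± 0.29, Ipo7 2.04 ± 0.23, Mat2a 2.26 ± 0.28 and Usp14 1.92 ± 0.24. Fitted effects had opposite signs in 20 of the 36 genes. Ephb2, the gene of the sorted protein, stood at 95.7 ± 40.9 CPM in WT and 32.5 ± 2.598 CPM in KO EphB2-negative cells. The crypt score was -2.24 and -4.54 in the WT and -5.35 and -5.68 in the KO EphB2-negative libraries. A larger part of crypt cells in WT EphB2-negative libraries would also give stem cell genes a positive and absorptive genes a negative difference. This cannot be told apart here from an effect of genotype.

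Among lists, median differences above 0 were 1.39 for stem cell, 1.16 for Wnt target, 1.29 for cell cycle, 1.74 for goblet and 3.05 for Paneth cell genes. Those below 0 were -2.26 for absorptive enterocyte, -1.37 for suckling enterocyte, -1.59 for adult enterocyte, -4.70 for tuft cell, -0.71 for NF-κB target, -0.68 for fatty acid oxidation and -2.53 for distal small intestine genes. With an estimated correlation the adjusted p of each of these was 0.61 or more. Without WT EphB2-negative replicate 1, Wnt targets and NF-κB targets no longer passed (camera adjusted p = 0.13 and 0.20), and the medians of stem cell, cell cycle and suckling genes were 0.75, 0.48 and -0.81.

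WT EphB2-negative replicate 1 lay between the EphB2-positive libraries and WT EphB2-negative replicate 2. A single share of EphB2-positive cells mixed into a population like that of WT EphB2-negative replicate 2 is argued against, since the absorptive enterocyte sum gave an EphB2-negative share of 33.9% and the pan-leukocyte sum 6.18%, and its pancreas acinar sum of 1831 CPM lay above both ends. An EphB2-positive library with the wrong label would need an absorptive sum in the range of the WT EphB2-positive libraries, but the sum was 2.63 times the higher of these, where their own ratio was 1.53. A swap of labels within WT would leave an EphB2-positive library as far from its group as this library was. The chi-square per degree of freedom of the WT EphB2-positive pair was 3.84, against 24.2 for the WT EphB2-negative pair. It lay above the KO EphB2-positive pairs at 1.93 to 2.23 and below the KO EphB2-negative pair at 4.32. The labels give no difference between the WT EphB2-negative libraries, so no biological explanation was tested, and a piece of gut with other cell proportions stays open, as does pancreas in the dissection.

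Of antimicrobial genes, 8 of 13 tested stood higher in KO than in WT EphB2-positive libraries. EphB2-negative cells carried into the KO EphB2-positive libraries would have to supply 48.6% of the KO EphB2-negative level, where the absorptive enterocyte sum allows 7.95% on average. Leukocytes, which a sort on EphB2 would remove, would have to supply the same 48.6%, where the pan-leukocyte sum allows 8.26%. Of the pan-leukocyte genes, none of which another list holds, Ptprc and Coro1a (named after their values were seen) stood at 0.171 and 0.33 CPM in KO EphB2-positive and 128 and 235 CPM in KO EphB2-negative cells, and Lcp1, the highest, at 91.05 and 362 CPM. Goblet and Paneth cells were not covered by these tests. Goblet genes summed to 3392 CPM on average in KO EphB2-positive and 6448 CPM in KO EphB2-negative libraries, and Paneth genes to 784 and 337 CPM. These sums set no such low limit, so goblet or Paneth cells as a source of the rise were not argued against. Expression of the antimicrobial genes by EphB2-positive cells that lack IκBα may account for the rise, as a hypothesis. A litter that coincides with genotype, which the labels do not give, was not tested and stays open. Single-cell RNA from sorted EphB2-positive cells of KO and WT littermates would bear on both. It would not tell whether loss of IκBα acts within these cells or through other cells.

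Of absorptive enterocyte and fatty acid oxidation genes, 9 of 25 and 8 of 15 tested stood lower in KO than in WT EphB2-positive libraries, and 1 of each stood higher. Cells like those of the WT EphB2-negative libraries carried into the WT EphB2-positive libraries would need a single share for all 8 absorptive genes that fell and reached 10 CPM in WT, but Dgat1 needs at least 32.8% and Fabp1 allows at most 9.33%. This form was settled on after shares of single genes had been seen and other forms weighed, and the sum over the whole absorptive list, with a share of 9.27%, excludes nothing by itself. For the fatty acid oxidation genes that fell, the sum needs at least 42.96%, and the absorptive genes that fell allow at most 25.7%. By gene, the lowest share needed ran from 7.33% to 79.0%, so this holds for the sum and not for each gene. Carried-over cells could still supply part of the difference, cells of another kind were not tested, and lower expression in EphB2-positive cells that lack IκBα stays a hypothesis. Litter is open as above, and the same single-cell measurement in littermates would bear on this too, with the same limit.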

How the results depend on the processing

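The crypt score and leaving WT EphB2-negative replicate 1 out of comparisons it is not part of were chosen after seeing the data, the other settings before. For KO against WT in EphB2-positive cells, the main count of 1746 stayed within 1.5 times with DESeq2's size factors (1775), no filter (1625), the stricter filter (1753) and DESeq2 (1431). It was 3353 with the pan-leukocyte score, 3141 with the crypt score, 3734 with the 2 groups alone and 3470 with voom and quality weights. Leaving out a library gave 568 to 3449. In EphB2-negative cells the count of 3456 was 1779 with the crypt score, 149 alone and 1516 with voom and quality weights, and 1096 to 5834 without a library. DESeq2's size factors gave 1810 up and 1581 down there. For the sort in WT, 513 became 72 with the pan-leukocyte score, 1 alone, 942 with DESeq2, 281 with voom and quality weights, and by edgeR 0 (2052 at an unadjusted p under 0.05) to 5009 without a library. For the sort in KO, 6428 became 1018 with the pan-leukocyte score, which nearly coincides with the sort there, and the difference of the genotype effect, 1430 genes, ran from 32 to 3996 without a library. Leaving out a library also leaves fewer residual degrees of freedom, and a group left with 1 library is assumed to vary like the others. The main fit shares 1 spread per gene over all groups. The chi-square per degree of freedom was 24.2 for the WT EphB2-negative replicates and 1.93 to 4.32 for the other pairs. So its p-values can be too small where that group is compared and too large where it is not. With the compared groups alone, counts fell to 149 and 1 with that group and rose to 3734 and 7290 without it. Other causes were not tested.

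The replicate numbers in the titles and the codes in the file names pair the WT libraries of the 2 sorts alike, with a residual correlation of 0.13; residuals of 2 replicates mirror each other, so this is 1 comparison. In KO they differ: libraries of the 2 sorts with the same number had 0.04 and -0.07, and those with the same code 0.07 and 0.11. Over all pairs with the same number, across genotypes too, the values ran from -0.07 to 0.13, so the numbers were not taken to pair the libraries. With the number as a block the counts were 1055 for KO against WT in EphB2-positive cells and 895 for the difference, and the code as a block moved the count for the sort in WT from 513 to 1248. The code cannot enter the genotype comparisons as a fixed block, since each code has 1 genotype.

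In EphB2-positive cells, the stem cell median of -0.31 and the fetal median of 0.26 did not pass with camera, and passed with fry for change in either direction (adjusted p = 1.7e-04 and 6.9e-04), which compares a list with no other genes. Over its alternatives the fetal adjusted p reached 0.94, and the median was -0.10 with the 2 groups alone. The stem cell median for the sort in WT, 1.24, was lost with an estimated correlation (adjusted p = 0.27), and was 0.27 with the pan-leukocyte score (adjusted p = 0.11). Of named genes that passed, 33 of 58 in EphB2-positive cells, 12 of 69 in EphB2-negative cells, 0 of 15 and 2 of 17 for the sort in WT and KO, and 10 of 36 for the difference kept their call in each setting. For the difference, 16 kept it without WT EphB2-positive replicate 1, 10 without WT EphB2-positive replicate 2 and 10 without KO EphB2-negative replicate 2.

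For KO against WT, most tested printed genes that had not passed did pass with the same sign in some other setting. Not passing in the main fit is thus no firm sign of no change. Signs turned for some printed genes that had not passed. In EphB2-positive cells Ephb2 was -0.019 with the crypt score. Mki67 was 0.0019 with the block, 0.011 with the pan-leukocyte score and -0.15 to 0.066 without a library. Without a library Chga ran over -0.28 to 0.75. Clu ran over -4.92 to 0.00, which is no turn of sign. The 0.00 stands for no Clu reads in either group once WT EphB2-positive replicate 1 is left out. In EphB2-negative cells the crypt score gave 0.15 for Ascl2, 0.49 for Axin2, -0.10 for Clu, -0.42 for Alpi, -1.23 for Lyz1 and -0.37 for Tnfaip3. There the pan-leukocyte score gave 0.37 for Axin2, -0.14 for Clu and -1.07 for Lyz1. Voom gave -0.019 for Clu and 0.095 for Muc2 with quality weights, and -0.012 and 0.072 with the code as a random block. Without a library the ranges were -1.65 to 0.11 for Axin2, -0.56 to 0.42 for Clu, -2.26 to 0.060 for Sis, -1.62 to 1.81 for Muc2 and -0.93 to 1.54 for Lyz1. Muc2 passed in opposite directions, at -1.62 without WT EphB2-negative replicate 1 (adjusted p = 0.046) and 1.81 without WT EphB2-negative replicate 2 (adjusted p = 0.036), and it was -2.09 with the pan-leukocyte score (adjusted p = 0.039). For the sort in WT, Ephb2 was -0.15 with the pan-leukocyte score. Of genes that had passed, Ngp in EphB2-negative cells was -1.30 with the crypt score (adjusted p = 0.52) and Il22 for the sort in KO 24.38 with the pan-leukocyte score (adjusted p = 0.0026). The cause was not tested. The simulated data had 1 spread per gene in all groups. For KO against WT in EphB2-positive cells, 37.5% of 2-fold and 80.6% of 4-fold changes were recovered. The shares were 21.6% and 78.6% in EphB2-negative cells, and 0% and 47.4% for the difference. False calls made up 6.92%, 6.36% and 8% of the calls in these comparisons. Smaller changes can thus be missed at this size, and recovery at the unequal spread of these libraries was not tested.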

Other observations

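The 6 lists here, and the genes named from them, were chosen after their values were seen, so all their tests were chosen only after the result was seen. In KO EphB2-positive cells, 8 of 14 tested interferon-gamma-inducible GTPase genes rose and 0 fell (median log2 fold change 3.33, camera adjusted p = 1.6e-16, adjusted p = 0.096 with an estimated correlation). Igtp stood at 121 ± 18.7 against 3.93 ± 2.77 CPM. Of antigen presentation genes, 10 of 15 rose (median 2.27, camera adjusted p = 4.0e-13, adjusted p = 0.096 with an estimated correlation), and Psmb8, of the immunoproteasome, stood at 184 ± 8.71 against 38.1 ± 7.89 CPM. In EphB2-negative cells, 10 of the GTPase genes and 11 of the antigen presentation genes rose (camera adjusted p = 2.3e-12 and 6.3e-13), calls that were lost with an estimated correlation (adjusted p = 0.16 and 0.16), and neither list's difference between the sorts passed (camera adjusted p = 0.40 and 0.40).

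Of aminoacyl-tRNA synthetase genes, 10 of 20 tested rose and 0 fell in KO EphB2-positive cells (median 0.49, camera adjusted p = 1.2e-06, adjusted p = 0.18 with an estimated correlation), with Wars at 367 ± 52.9 against 125 ± 9.72 CPM. In EphB2-negative cells 5 rose and 3 fell (camera adjusted p = 0.55), and the difference between the sorts had a median of 0.53 (camera adjusted p = 0.015, adjusted p = 0.97 with an estimated correlation). Of glucuronyl- and sulfotransferase genes, which conjugate drugs and steroids, 9 of 14 tested fell and 0 rose in KO EphB2-positive cells (median -2.38, camera adjusted p = 3.0e-12, adjusted p = 0.089 with an estimated correlation) and 9 of 14 fell and 1 rose in EphB2-negative cells (median -1.95, camera adjusted p = 6.6e-05, adjusted p = 0.16 with an estimated correlation). Ugt2b5 stood at 3.11 ± 2.01 against 32.7 ± 3.23 CPM and Ugt1a1 at 1.67 ± 0.622 against 33.7 ± 6.72 CPM in EphB2-positive cells. Ugt1a genes share exons, so reads could not always be told apart.

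In EphB2-negative cells, 5 of 6 tested cytokine genes of lymphocytes rose in KO (camera adjusted p = 8.3e-05, adjusted p = 0.18 with an estimated correlation). Lymphoid genes summed to 29.3 and 800.4 CPM in WT and 1089 and 391 CPM in KO EphB2-negative libraries, so the WT and KO ranges overlapped. Mast cell protease genes were lower in EphB2-positive than in EphB2-negative cells, 6 of 6 in WT (camera adjusted p = 8.2e-11, adjusted p = 0.0057 with an estimated correlation) and 6 of 6 in KO (camera adjusted p = 3.6e-04, adjusted p = 0.055 with an estimated correlation). Reads outside annotated genes made up 11.1% to 14.7% of the counted reads in WT and 9.97% to 11.1% in KO libraries.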
